A study of Mus musculus with 6 samples.

How the data were processed

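Polyadenylated RNA was extracted with TRIzol from testes of mice at postnatal day 19 and made into libraries with a NEBNext Ultra kit, per the labels. Each of the 6 libraries was deposited as a column of raw gene counts (unit counts), and all 6 entered the analysis, 3 per group. Per the submitters' processing notes reads were aligned with STAR 2.6.0 to mm10. The counting tool, the gene annotation used for counting and its strand setting are not given in the sources used here. Depth was read from the counts themselves (15.3 to 27.7 M reads per library), and every column of the table that belongs to a sample was used.

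The table held 55487 gene identifiers. Symbols, positions and exons were taken from GENCODE M21 (GRCm38), in which 55227 identifiers were found and 260 were not; the latter held 0.0238% of all counts, stayed in the tests and belong to no list. Of 127 genes named by the rule 31 share exonic sequence with another annotated gene. Since it is not known whether reads were counted by strand, values of genes that overlap another gene on the opposite strand are uncertain, as are those of near-identical copies.

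The comparison was fitted on raw counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as its argument, libraries were scaled by TMM (factors 0.897, 0.875 and 0.844 for control and 1.14, 1.139 and 1.163 for dsfb), and the group was the only term of the model (estimateDisp, glmQLFit, glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes are edgeR's, with a prior count of 0.125, and the SE was taken as the absolute log2 fold change over the square root of F. CPM are on TMM-scaled library sizes and are given as mean ± SD of n = 3. For a gene with 0 counts in dsfb the fold is a lower bound that puts a floor of 3 counts over the group, and for 1 to 3 counts the ratio is given with a 95% counting interval. Such intervals and bounds cover counting error only and leave out the spread between animals.

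Gene sets were tested two-sided with camera in limma 3.58.1 on voom values with an inter-gene correlation of 0.01, each set against all other tested genes, adjusted by Benjamini-Hochberg over 28 sets. These were 26 gene lists (pathways, cell type markers and, as signs of sample quality, immediate early genes and mitochondrial transcripts) fixed before the data were examined and the X-linked and Y-linked genes. Of 377 listed symbols 365 matched directly, 8 by synonym and 4 did not match; 354 distinct members were tested and 10 of them stand in more than one list. Gene counts in a list use the adjusted p over all genes unless "adjusted over the list alone" is written. Shares of counts were compared by exact permutation of library labels, where 3 against 3 gives 10 splits and a smallest two-sided p of 0.1.

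Genes were named by a rule. It took Hormad1 and Hormad2, the 10 largest rises and the 10 largest falls among genes that passed the test, and up to 4 members of each list or set with the smallest p. The largest rises and falls needed a mean of at least 1 CPM, a symbol that is not a clone or predicted name, and groups whose libraries do not overlap, which left 5248 rises and 4750 falls to choose from. With no difference, 10% of genes would have such groups. Some genes that the rule takes are not reported here.

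Alternatives planned beforehand were RLE, upper-quartile, library-size-only and autosomal TMM scaling; no filter beyond 1 read, or a mean of at least 1 CPM; the Wald test of DESeq2 1.42.0 (207 genes with no adjusted p); limma-voom; a threshold of 2-fold; leaving out each library; a replicate block; and, for sets, camera with an estimated correlation and fry. Thinning of all libraries to the smallest total, the libraries numbered 1 and 2 only, and centring on autosomal Sertoli markers were added after the data had been seen, the thinning before its own count was known.

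The fit was first run on simulated counts of 19096 genes with known changes. It recovered 5 of 67 genes changed 1.5-fold, 26 of 67 changed 2-fold and 51 of 66 changed 4-fold, and called 5 of 18866 unchanged genes. The set test called the shifted set and not the unchanged set. Genes were simulated independently of each other and only a small part was changed. The run therefore does not cover sets of correlated genes (estimated correlation up to 0.95 in the lists, for spermatids). Nor does it cover data in which 66.9% of genes pass. No pair of libraries within a group was alike within sampling noise (chi-square over degrees of freedom 3.82 to 65).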

Results

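Testes of juvenile mice were profiled by sequencing of polyadenylated RNA at postnatal day 19, an age at which the first wave of spermatogenesis has brought many germ cells to the pachytene stage of meiosis. The 6 libraries form 2 groups of 3. One group is labelled control, and the other is labelled dsfb and, per the title of the series, carries SFB alleles of both Hormad1 and Hormad2, which encode proteins of the meiotic chromosome axis. The labels state that the testes came from different mice, so n = 3 per group counts separate animals. The control libraries held 23983373, 27707291 and 25684743 counted reads (replicates 1, 2 and 3) and the dsfb libraries 17306363, 15335130 and 15957354, so depth differed between the groups (25.8 ± 1.85 M against 16.2 ± 1.01 M reads, SD). The comparison the design implies is dsfb against control, which asks how the testis transcriptome differs when both genes carry the altered allele. Gene positions are given for mm10 (GRCm38).

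Transcripts of late meiotic and postmeiotic germ cells were lower in the dsfb testes, while X-linked transcripts and markers of Sertoli cells were higher. Of 19826 genes tested, 6080 rose and 7176 fell (edgeR adjusted p under 0.05), so that 66.9% passed the test and 45.9% of those rose. The falls were larger than the rises: 5306 genes fell and 2608 rose by at least 2-fold, and 2075 fell and 13 rose by at least 16-fold. Among the genes that fell, 584 had 0 counts in all 3 dsfb libraries. The split of calls depended on the scaling. With library size as the only scaling 8936 genes rose and 5732 fell (60.9% of calls higher), and with upper-quartile scaling 8187 rose and 6126 fell (57.2% higher). These scalings moved the median log2 fold change of all genes by 0.396 and 0.278. With no filter on low counts 4869 rose and 8839 fell (35.5% higher, median moved by -0.303).

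Both targeted genes were still transcribed in the dsfb testes. Hormad1 (ENSMUSG00000028109, chromosome 3, 95559677 to 95587671, plus strand) was at 446, 486 and 209 CPM (counts scaled to library size) in control replicates 1, 2 and 3 and at 217, 246 and 243 CPM in dsfb replicates 1, 2 and 3. Its log2 fold change of -0.69 (SE 0.28) did not pass the test (edgeR adjusted p = 0.0597). With TMM scaling control replicate 3 lay at the level of the dsfb libraries, and without that library the value was -1.02 (edgeR adjusted p = 1.57e-10). With all libraries Hormad1 passed with RLE scaling (edgeR adjusted p = 0.0382), with no filter on low counts (edgeR adjusted p = 0.0247) and with the DESeq2 Wald test (adjusted p = 0.00496). Upper-quartile and library-size-only scaling moved the median of all genes up by 0.278 and 0.396, which makes the fall of Hormad1 smaller. Hormad2 (ENSMUSG00000020419, chromosome 11, 4345814 to 4441105, minus strand) fell from 52.7 ± 8.79 to 27.1 ± 1.79 CPM (SD, n = 3), a log2 change of -0.96 (SE 0.14, edgeR adjusted p = 0.000757). The label does not say whether the alleles are meant to lower the transcript, and the counts cover whole genes, so these levels do not check the genotype.

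**Figure D1:**
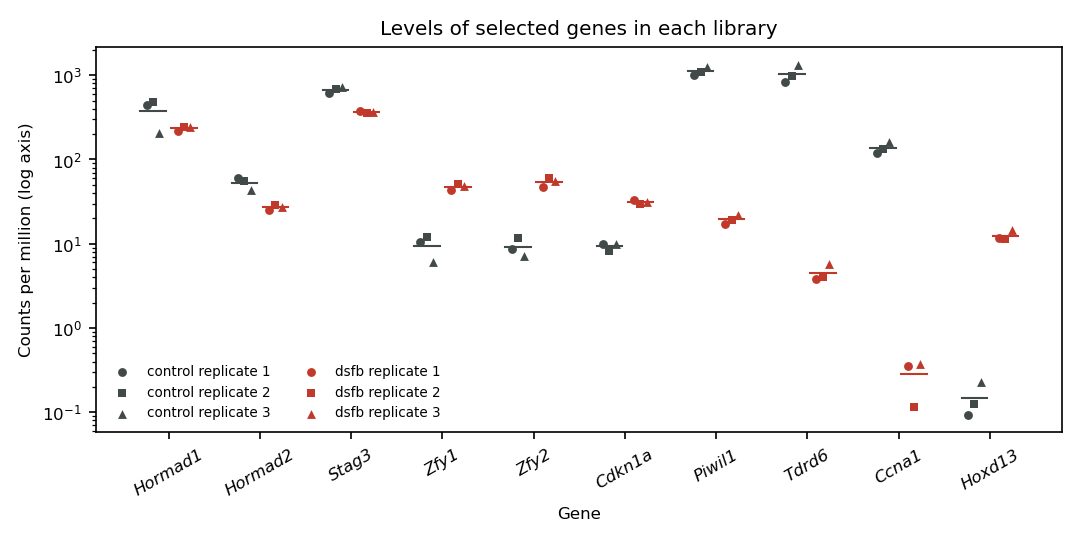
Levels in CPM (log axis) of selected genes in each of the 6 libraries, with a marker shape per replicate, controls in grey, dsfb in red and a short line at each group mean. Hormad1 in control replicate 3 sits at 209 CPM beside the dsfb libraries, while Piwil1, Tdrd6 and Ccna1 are lower and Zfy1, Zfy2, Cdkn1a and Hoxd13 higher in all 3 dsfb libraries.

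The 10 largest rises by the fixed rule were in genes with a mean under 1 CPM in control testes. Hoxd13, a homeobox gene of distal limb and genital development on chromosome 2 (74668310 to 74671599), rose from 0.15 ± 0.0728 to 12.5 ± 1.68 CPM, an 80.9-fold change (log2 6.34, SE 0.34, edgeR adjusted p = 3.94e-06). The forkhead genes Foxa2 and Foxd2 rose 20.3-fold and 13.7-fold. Fam19a1 rose 22.6-fold. Evx1 (18.6-fold) and Evx1os (13.7-fold) also rose, but they overlap on opposite strands and the strand setting of the counting is not given in the sources used here, so the pair is uncertain. Rhox2h, Rhox2c and Rhox2d, near-identical X-linked homeobox copies between which reads could be divided, rose 20.2-fold, 12.6-fold and 10.8-fold and are uncertain singly. Several of these folds moved when 1 control library was left out: the log2 change was 5.09 for Foxa2, 4.32 for Rhox2c and 4.45 for Rhox2d without control replicate 2, 5.69 for Evx1 and 3.06 for Rhox2c without control replicate 3, 3.6 for Evx1 without control replicate 2 and 4.53 for Evx1os without control replicate 1, against 4.34, 3.66, 3.43, 4.22 and 3.77 for Foxa2, Rhox2c, Rhox2d, Evx1 and Evx1os with all libraries.

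The largest falls by the same rule were, except for Cmtm2b, in genes with 0 counts in the 3 dsfb libraries, for which only a lower bound can be given (a floor of 3 counts over the group). Hrasls5, a phospholipase and acyltransferase gene on chromosome 19 (7612541 to 7639642), was at 434 ± 115 CPM in control and at least 8010-fold lower in dsfb. Slco6c1, an organic anion transporter of the testis, was at least 4030-fold lower, Abca14 at least 3110-fold, Tekt3, a tektin of the sperm flagellum, at least 2380-fold and Pom121l12 at least 1350-fold. Cmtm2b had 1 count in the dsfb libraries and 15872 in the controls, a ratio of 13100 with a 95% counting interval of 2360 to 518000. Without dsfb replicate 1, the library with that count, Cmtm2b had 0 counts in dsfb. Its log2 change then went from -13.26 to -15.25, a value that depends on the prior count and is not a measured size. The remaining falls drew much of their control level from control replicate 3. Cfap58 was at 138 CPM there and at 41.0 and 37.3 CPM in replicates 1 and 2, and was at least 1310-fold lower in dsfb, or at least 724-fold without that library. The corresponding bounds were 1130 and 689 for Tex21 and 1090 and 337 for Spz1. Intervals and bounds cover counting error only.

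Genes of mid to late pachytene spermatocytes, spermatids and the flagellar axoneme fell as groups. All 20 tested markers of mid to late pachytene spermatocytes fell (median log2 fold change -4.70, camera adjusted p = 9.68e-11). The call was lost with an estimated correlation (adjusted p = 0.355 with an estimated correlation). Crisp2, a cysteine-rich secretory protein of the sperm head and tail, fell 228-fold from 1154 ± 119 to 5.06 ± 0.611 CPM. Ldhc, the testis-specific lactate dehydrogenase, fell 267-fold from 2900 ± 537 to 10.8 ± 1.10 CPM, and Adam3, a sperm surface protein, went from 42668 to 6 counts (log2 -12.45, SE 0.32, edgeR adjusted p = 1.88e-07). Nme8 kept 2 counts in dsfb against 7006 in control, a ratio of 2900 with a counting interval of 802 to 23900. All 23 tested spermatid genes fell (median -6.74, also with 3 genes set at their bounds, camera adjusted p = 0.00624, adjusted p = 0.654 with an estimated correlation). Among them Acr, which encodes the acrosomal protease acrosin, had a log2 change of -8.38 (SE 0.47), Zpbp of -3.77 (SE 0.13), Catsper2, a sperm calcium channel subunit, of -3.68 (SE 0.23) and Acrv1 of -7.51 (SE 1.18), or -5.81 without control replicate 3. Without dsfb replicate 3 the value for Acr was -9.35. Adam3, Zpbp and Catsper2 share exonic sequence with genes on the opposite strand. All 26 axoneme genes fell (median -5.12, camera adjusted p = 2.47e-11, adjusted p = 0.398 with an estimated correlation), with log2 changes of -7.83 for Spag17, -7.21 for Tekt1, -6.29 for Spag6l and -5.48 for Cfap43. Spag17 and Cfap43 share exonic sequence with other genes. The control libraries were not alike in these groups: the spermatid median of control replicate 3 lay 3.29 log2 units above the mean of the other controls, against 0.28 for the pachytene list and 0.46 for the axoneme list. Without that library the spermatid median was -4.43 and 20 of 21 tested genes fell, and without control replicate 1 it was -7.43. Of the 23 spermatid genes 20, 19 and 18 were still called without dsfb replicates 1, 2 and 3.

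**Figure D2:**
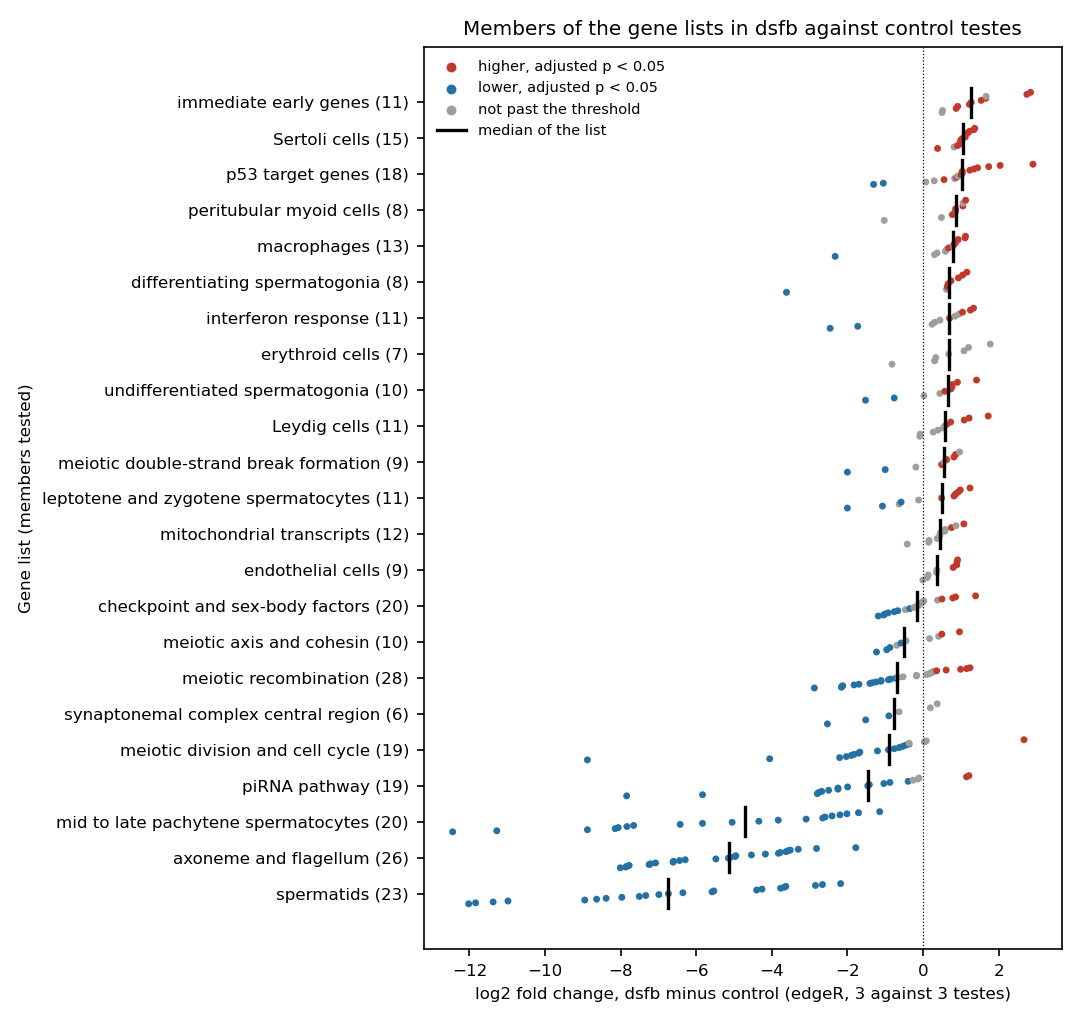
Log2 fold change (dsfb minus control, x axis) of each tested member of the gene lists (y axis, number tested in brackets), 1 point per gene, coloured by edgeR adjusted p and direction, with a black bar at the list median. The spermatid, axoneme and pachytene lists lie wholly below 0 (medians -6.74, -5.12 and -4.70), and the Sertoli list lies wholly above it (median 1.05).

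Genes of the piRNA pathway, autosomal retrogenes and genes of the meiotic divisions were lower as well. In the piRNA pathway, which silences transposons in germ cells, 14 of 19 genes fell and 2 rose (median -1.46, camera adjusted p = 0.000108, adjusted p = 0.355 with an estimated correlation). Piwil1, the PIWI protein of pachytene spermatocytes (chromosome 5, 128702524 to 128755474), fell 57.1-fold from 1110 ± 130 to 19.4 ± 2.37 CPM, and Tdrd6, a tudor-domain protein of the chromatoid body, fell 229-fold from 1044 ± 266 to 4.55 ± 1.11 CPM. Tdrd5, which overlaps a gene on the opposite strand, fell 6.77-fold and Pld6 6.95-fold. The members that rose, named after their values were seen, were Tex19.1 (log2 1.22, SE 0.09) and Piwil4 (1.15, SE 0.26), the latter also overlapped on the opposite strand. All 10 autosomal retrogene copies of X-linked genes fell (median -2.05, camera adjusted p = 0.000322, adjusted p = 0.355 with an estimated correlation). Cetn1, a centrin of the male germ line, fell 360-fold, Pgk2, the phosphoglycerate kinase of late germ cells, 286-fold, Zfa-ps 24.2-fold and Pdha2 4.63-fold. Reads of such copies can be divided with their parent genes. Among 19 genes of meiotic division and the cell cycle 15 fell and 1 rose (median -0.91, camera adjusted p = 0.000625, adjusted p = 0.398 with an estimated correlation). Ccna1, the germ cell A-type cyclin, fell 471-fold from 138 ± 22.5 to 0.283 ± 0.146 CPM, Aurkc 16.6-fold, Ccnb2 4.62-fold and Pttg1, which encodes securin, 3.54-fold. Ccna1 overlaps a gene on the opposite strand. The member that rose was X-linked Ccnb3 (log2 2.67, SE 0.31), a cyclin of early meiotic prophase, named after its values were seen.

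Genes of the chromosome axis, double-strand breaks, recombination and the meiotic checkpoint moved in both directions, and neither these lists nor that of synapsis passed the set test. Of 10 axis and cohesin genes 4 fell and 2 rose (median -0.51, camera adjusted p = 0.534): Sycp2 fell 2.35-fold, Hormad2 1.95-fold and the cohesin gene Stag3 1.84-fold, from 673 ± 50.9 to 367 ± 12.7 CPM, while Smc3 rose 1.41-fold. The other members that passed, named after their values were seen, were Smc1b (log2 -0.58) and Rad21l (0.96). In the list of the synaptonemal complex central region 3 of 6 genes fell and 0 rose by edgeR (median -0.77, camera adjusted p = 0.259). Syce1 fell 5.77-fold and Syce3 2.86-fold. Tex12 fell 1.87-fold (edgeR adjusted p = 0.0302), a call that was lost without control replicate 1 or 2 or any 1 of the dsfb libraries (edgeR adjusted p = 0.0687 to 0.11). Syce2 was at 64.7 ± 13.9 and 84.0 ± 2.94 CPM (edgeR adjusted p = 0.0639, or 0.0369 without control replicate 1). Without control replicate 1 the list had 1 rise and 2 falls, and without control replicate 3 its set test gave a camera adjusted p of 0.0483. Of 9 genes of double-strand break formation 4 rose and 2 fell (median 0.56, mean 0.13, camera adjusted p = 0.428, with fry pointing down). Spo11, which makes the breaks, fell 4-fold from 126 ± 6.49 to 31.5 ± 3.85 CPM, Ankrd31 fell 2.00-fold, and Mei1 and Prdm9 rose 1.76-fold and 1.82-fold, the call for Prdm9 being lost without dsfb replicate 1 (edgeR adjusted p = 0.0575), where 1 gene of the list rose.

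Among 28 recombination genes 14 fell and 5 rose (median -0.69, camera adjusted p = 0.0937, or 0.0243 without control replicate 3), with 3 rises without dsfb replicate 1. Prr19 and Cntd1, which act in crossover formation, fell 7.34-fold and 4.47-fold, 4930432K21Rik (Brme1) 4.44-fold and Psmc3ip, a partner of the strand exchange proteins, 4.36-fold. Psmc3ip and Cntd1 overlap genes on the opposite strand. Among 20 checkpoint and sex-body factors 7 fell and 4 rose (median -0.15, camera adjusted p = 0.421, pointing up with library size as the only scaling). Mdc1, which spreads the DNA damage response along the sex chromosomes, fell 2.06-fold from 702 ± 37.7 to 341 ± 8.75 CPM, Rad18 2.27-fold, Rad9b 2.01-fold and the kinase gene Atr 1.90-fold. Rad9b and Atr share exonic sequence with other genes.

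X-linked genes were higher in dsfb. Of 766 tested X-linked genes 567 rose, 65 fell and 134 did not pass (578 rose and 66 fell adjusted over the list alone). The median log2 fold change was 1.03, against -0.03 over the autosomes, on which the medians of single chromosomes ranged from -0.27 to 0.11 and 28.9% of genes rose. The X-linked set passed camera (adjusted p = 8.3e-18) and not with an estimated correlation (adjusted p = 0.398 with an estimated correlation). The X chromosome supplied 1.43 ± 0.23% of all counts in control and 3.97 ± 0.0855% in dsfb (SD, n = 3), 2.78 times as much. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Tex13c2 (7.08-fold), the creatine transporter Slc6a8 (6.49-fold), the ribosome biogenesis gene Las1l (2.97-fold) and Zmym3 (2.58-fold, from 146 ± 3.49 to 378 ± 9.21 CPM) all rose and were the members named by the rule. Akap4, an X-linked gene of the sperm fibrous sheath in the spermatid list, named after its values were seen, fell (log2 -6.74, SE 1.32) and was at 15.2, 14 and 192 CPM in control replicates 1, 2 and 3, with a log2 change of -4.43 without the last. In the same libraries the Sertoli markers were 2.07-fold higher at their median. That list itself holds X-linked genes, and its 11 autosomal markers had a median log2 fold change of 1.

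**Figure D3:**
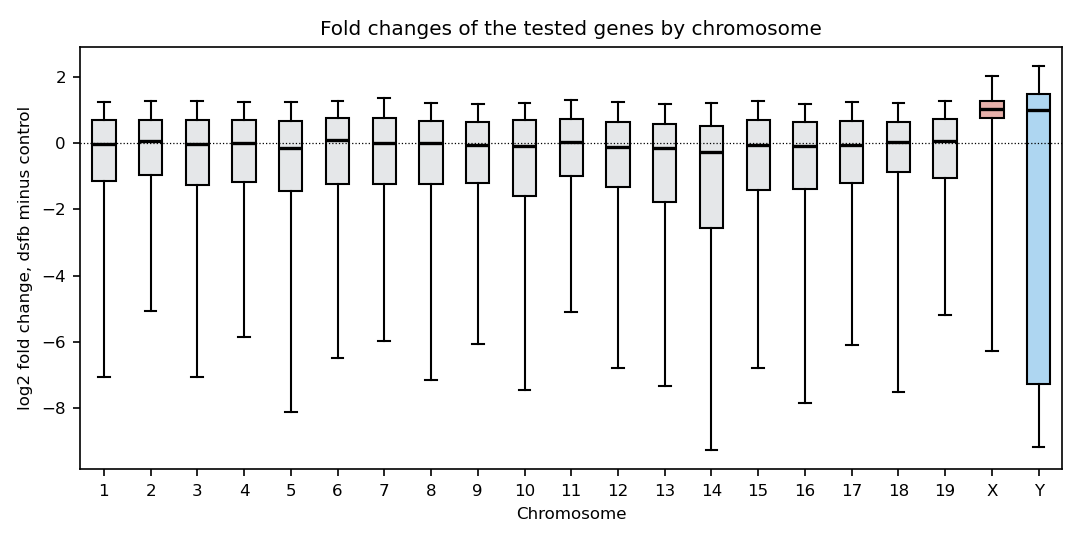
Log2 fold change (dsfb minus control, y axis) of the tested genes on each chromosome (x axis); boxes span the quartiles, whiskers the 5th to 95th percentile and black lines mark medians. The X chromosome has its median at 1.03 while those of the autosomes lie between -0.27 and 0.11, and the Y chromosome combines a median of 1.01 with genes far below 0.

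All 29 tested sex-linked genes that are silenced at pachytene rose (median 1.19, camera adjusted p = 4.31e-10, adjusted p = 0.398 with an estimated correlation). Zfy2, a Y-linked zinc finger gene (chromosome Y, 2106015 to 2170409), rose 5.92-fold from 9.19 ± 2.35 to 54.5 ± 6.30 CPM. Rhox13 rose 3.43-fold, the histone demethylase gene Kdm5c 2.17-fold and the ubiquitin ligase gene Cul4b 1.74-fold. The smallest median of this list in a dsfb library was 0.98 and the largest 1.15 log2 units above control replicates 1 and 2, while control replicate 3 lay at -0.61. Of 20 tested Y-linked genes 12 rose and 6 fell (median 1.01, mean -1.50, camera adjusted p = 0.111, adjusted p = 0.475 with an estimated correlation). Zfy1 rose 4.99-fold and Eif2s3y 1.88-fold. The multi-copy gene Sly, whose reads cannot be assigned to a single copy, had 0 counts in dsfb and was at least 64.2-fold lower. The direction of the Y-linked set turned when a dsfb library was left out (camera adjusted p = 0.552, 0.304 and 0.396 without replicates 1, 2 and 3), settings in which 39, 38 and 39 genes were tested and 22, 22 and 23 fell, and the set passed as higher without control replicate 1 (0.0303) or 3 (0.0162). With no filter on low counts 402 Y-linked genes were tested and the set passed as lower (median -3.74, camera adjusted p = 0.000149), and it passed as higher with a mean of at least 1 CPM (0.00558) and with DESeq2 (0.0349).

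Markers of spermatogonia and of early meiotic cells had medians above 0, and none of these 3 lists passed the set test. Of 10 tested genes of undifferentiated spermatogonia 6 rose and 2 fell (median 0.66, camera adjusted p = 0.254), and 1 fell without control replicate 2 or dsfb replicate 2 or 3. Zbtb16 and Lin28a, factors of spermatogonial progenitors, rose 1.66-fold and 1.88-fold, and Lhx1 rose 2.67-fold. Id4, an inhibitor of DNA binding, fell 2.87-fold. Lin28a and Id4 overlap genes on the opposite strand. Of 8 genes of differentiating spermatogonia 6 rose (7 adjusted over the list alone) and 1 fell (median 0.70, camera adjusted p = 0.0802). Kit, the receptor of stem cell factor, rose 1.67-fold from 59.3 ± 8.63 to 99.0 ± 4.16 CPM, Sohlh1 2.24-fold and Ccnd2 2.07-fold, while Dmrtb1, a regulator of the entry into meiosis, fell 12.2-fold. Ccnd2 is overlapped on the opposite strand. Of 11 leptotene and zygotene markers 6 rose and 3 fell (median 0.49, mean 0.08, camera adjusted p = 0.534, with fry pointing down). Without control replicate 3 there were 6 rises and 5 falls (median 0.29) and without dsfb replicate 1 there were 3 of each. Dmc1, the meiotic recombinase, rose 2.36-fold from 54.9 ± 16.1 to 130 ± 2.84 CPM and Meioc fell 2.10-fold. In these libraries the Sertoli markers were 2.07-fold higher at their median.

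Markers of somatic cells of the testis were mostly higher. Of 15 Sertoli genes 14 rose and 0 fell (median 1.05, camera adjusted p = 7.15e-06, adjusted p = 0.398 with an estimated correlation). Cldn11, a claudin of the blood-testis barrier, rose 2.29-fold from 222 ± 27.6 to 509 ± 10.8 CPM, Rhox8 2.54-fold, Tsx 2.07-fold and Dhh 2.00-fold, Tsx and Dhh sharing exonic sequence with other genes. Of 8 peritubular myoid genes 5 rose and 0 fell (median 0.86, camera adjusted p = 0.0412, adjusted p = 0.398 with an estimated correlation), among them the smooth muscle genes Myl9 (2.19-fold), Des (2.08-fold), Myh11 and Lmod1 (both 1.82-fold). Des overlaps a gene on the opposite strand. The call for peritubular myoid cells was lost with upper-quartile scaling (camera adjusted p = 0.0671), library size only (0.0836), a mean of at least 1 CPM (0.0571) and DESeq2 (0.0972). Of 13 markers of macrophages 7 rose (8 adjusted over the list alone) and 1 fell (median 0.80, camera adjusted p = 0.0457, adjusted p = 0.638 with an estimated correlation). The complement genes C1qa and C1qc rose 2.18-fold and 2.16-fold and Mrc1 1.6-fold, while the Fc receptor gene Fcgr3 fell 5.01-fold. The macrophage call was lost without control replicate 2 (camera adjusted p = 0.0722) or dsfb replicate 3 (0.0655), each with 3 rises, and with upper-quartile scaling (0.0684), library size only (0.0836), a mean of at least 1 CPM (0.0571) and DESeq2 (0.161).

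The other tissue markers did not pass as lists. Of 11 markers of Leydig cells 5 rose and 0 fell (median 0.57, camera adjusted p = 0.0526), with Nr5a1, the steroidogenic factor, at 2.33-fold and Scarb1 at 1.66-fold. The list passed without control replicate 1 (0.0325), control replicate 3 (0.0274, 8 rises) or dsfb replicate 3 (0.0151, 3 rises), and had 3 rises without dsfb replicate 1. Of 9 endothelial genes 4 rose and 0 fell (median 0.37, camera adjusted p = 0.104), with the cadherin gene Cdh5 at 1.74-fold, and 2 rose without control replicate 1 or 2 or dsfb replicate 1. Of 7 erythroid genes 0 passed with edgeR (median 0.68, camera adjusted p = 0.428), while 2 rose without control replicate 3 (median 0.22), and globin transcripts were low in both libraries numbered 3, at 0.001% of counts in control replicate 3 and 0.004% in dsfb replicate 3 against 0.018 to 0.036% elsewhere. Of 8 epididymis markers 1 was tested, Rnase10, which had 0 counts in dsfb and was at least 98.1-fold lower (camera adjusted p = 0.139).

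Targets of p53 and immediate early genes were higher as lists, the latter list being fixed as a sign of sample handling. Of 18 p53 targets 12 rose (13 adjusted over the list alone) and 2 fell (median 1.02, camera adjusted p = 0.00183, adjusted p = 0.398 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 3.34-fold from 9.38 ± 0.971 to 31.3 ± 1.96 CPM, the X-linked receptor gene Eda2r rose 7.51-fold and Sesn2 2.04-fold. Mdm2, which encodes the ubiquitin ligase for p53, fell 2.07-fold, and Zmat3, named after its values were seen, fell 2.48-fold. Of 11 immediate early genes 8 rose and 0 fell (median 1.28, camera adjusted p = 0.00183, adjusted p = 0.398 with an estimated correlation), among them the transcription factor genes Egr1 (2.90-fold) and Junb (2.42-fold) and the regulators Btg2 (3.16-fold) and Zfp36 (2.34-fold). Cdkn1a, Junb and Zfp36 overlap genes on the opposite strand. Sertoli markers were 2.07-fold higher in the same libraries. Of 11 interferon response genes 4 rose and 2 fell (median 0.70, camera adjusted p = 0.134), with Ifi27 and Irf7 at 2.38-fold and 2.52-fold higher and Cxcl10 5.49-fold lower. Irf7 and Cxcl10 share exonic sequence with other genes. The list had 1 fall without control replicate 1 or dsfb replicate 1 or 2.

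Levels of mitochondrial transcripts varied between libraries of a group. Of 12 tested, 2 rose and 0 fell (1 rose adjusted over the list alone; median 0.45, camera adjusted p = 0.104), and the list passed without control replicate 2 (0.0458) or dsfb replicate 3 (0.0273). Without control replicate 3 there were 5 rises and 1 fall (median 0.21), and without control replicate 1 or dsfb replicate 1 or 2 there was 1 rise. The respiratory chain gene mt-Co2 rose 2.12-fold from 22.0 to 46.6 CPM, and mt-Co3 1.69-fold from 21.8 to 36.7 CPM. Both levels were low next to mt-Nd4, at 1588 and 2154 CPM, which did not pass (edgeR adjusted p = 0.0976). All genes of the mitochondrial chromosome, a larger set than the list, took 2.73%, 2.58% and 1.30% of counts in control replicates 1, 2 and 3. In the dsfb replicates they took 4.17%, 4.14% and 3.17% (exact two-sided permutation p = 0.1, the smallest possible with n = 3).

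For the lists for which no such count is given, the counts adjusted over the list alone equalled those over all genes. In all, 13 of 28 sets passed camera with the preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.355), while 20 passed fry, a rotation test of the set on its own.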

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

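Apart from centring on Sertoli markers, no gene called in the main edgeR analysis was called in the other direction in any setting. The alternatives that thin libraries, keep libraries 1 and 2 only or centre on Sertoli markers were chosen after seeing the data, the thinning before its own count was known. With a 2-fold threshold 2608 genes were higher, and centring on autosomal Sertoli markers left 258 higher and 12331 lower, with 1104 genes going from higher to lower, which follows from the shift of all values by -1.04 by construction. Otherwise the cause was not tested. Camera with an estimated correlation gave adjusted p = 0.355 (pachytene, piRNA, retrogenes), 0.398 (axoneme, sex-linked silenced, division, p53, immediate early, Sertoli cells, peritubular myoid cells, X-linked genes), 0.638 (macrophages) and 0.654 (spermatids). Fry gave 0.0516 for spermatids, 0.11 for macrophages and 0.0127 for Y-linked genes, and turned double-strand break formation and the leptotene and zygotene list down (both 0.71). Checkpoint factors turned up with library size only (0.844). Markers of peritubular myoid cells lost the call under upper-quartile (0.0671), library size only (0.0836), mean CPM of at least 1 (0.0571) and DESeq2 (0.0972), and macrophages under these (0.0684, 0.0836, 0.0571, 0.161), thinning (0.0559), libraries 1 and 2 (0.0503) and without control replicate 2 or dsfb replicate 3, within 0.0134 to 0.0722 over the libraries left out. Y-linked genes turned down with no filter (0.000149, 402 tested, median -3.74) and without each dsfb library (0.552, 0.304, 0.396), within 0.0162 to 0.552 over the libraries left out, and passed as higher with mean CPM of at least 1 (0.00558) and DESeq2 (0.0349). Hormad1 passed with RLE (-0.78), no filter (-0.77), DESeq2 (-0.78), the block (-0.61) and libraries 1 and 2 (-1.01), and ranged from -1.02 to -0.49 over the libraries left out. Its fall becomes smaller with upper-quartile and library-size-only scaling, which moved the median of all genes up. Hormad2 ranged from -1.12 to -0.90 over the libraries left out. The replicate numbers were not taken as pairs, since the labels do not say that they mark any. Residual correlations of same-numbered libraries were 0.07, 0.06 and 0.12, the last above the preset bound of 0.1. Each library correlated best with its own number, a hint of pairing from the data only, which stays open. The replicate block gave 6228 genes higher and 7203 lower. Depth limits genes near a floor of 3 counts in 1 library (0.124 to 0.172 CPM), a higher level than the floor over a group used for the bounds.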

Other observations

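The groups of genes in this part were chosen after the results were seen, in part for genes named above, so their counts are given with no set test. Developmental transcription factor families moved in both directions: of 98 tested genes 46 rose and 19 fell (median 0.75). Beside Hoxd13 and Foxa2, Mafa rose 5.68-fold from 2.21 ± 0.485 to 12.6 ± 1.47 CPM and Nkx2-5 20.3-fold from near the floor, or 46.5-fold without control replicate 1. Without control replicate 2 the fold of Foxa2 was 34.0. Hoxa4 fell 20.3-fold from 49.9 ± 3.25 to 2.46 ± 0.496 CPM, Alx1 11.6-fold, Nkx6-2 18.6-fold and Foxj1, a regulator of motile cilia, 23.7-fold, or 10.7-fold without control replicate 3. Hoxa4, Alx1 and Nkx6-2 share exonic sequence with other genes. The Hox genes that passed went both ways: beside Hoxd13, Hoxd9 (2.98-fold), Hoxc4 (2.49-fold), Hoxb9 (2.37-fold), Hoxd10 (2.07-fold) and Hoxc6 (1.98-fold) rose, and beside Hoxa4, Hoxa3 (5.07-fold) and Hoxd8 (1.79-fold) fell. The call was lost for Hoxd10 without dsfb replicate 2 (edgeR adjusted p = 0.0598), for Hoxb9 without dsfb replicate 1 (0.0589) and for Hoxc6 without control replicate 2 (0.0525), dsfb replicate 1 (0.076) or dsfb replicate 2 (0.0586). Hoxa3 and Hoxd10 share exonic sequence with other genes. Total counts in control and dsfb were 10 and 697 for Hoxd13, 0 and 37 for Hoxd12, 8 and 9 for Hoxd11, 98 and 167 for Hoxd10, 3 and 20 for Hoxa13, 10 and 5 for Hoxb13, and 1 and 3 for Hoxc13. In the X-linked Rhox cluster 14 of 16 tested genes rose and 0 fell (median 2.08), with the Rhox2 copies uncertain singly. Of all tested X-linked genes 74% rose, and Rhox5 and Rhox8 also stand in the Sertoli list, so a rise as such is not particular to the cluster. The median of the cluster lay above that of all X-linked genes (1.03) and that of the Sertoli list (1.05).

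Among enzymes of glycolysis all 7 spermatogenic forms fell (median -7.07). Without control replicate 3 their median was -5.38, with log2 changes of -5.38 for Aldoart1, -4.90 for Aldoart2 and -0.90 for Gapdhs against -7.07, -7.06 and -2.85 with all libraries. Of 14 general forms of the enzymes and of a glucose transporter, Slc2a1, 9 rose and 4 fell (median 0.79). Pfkl rose 2.79-fold, Pgk1 2.46-fold, Pgam1 2.40-fold, Pkm 2.06-fold and Ldhb 1.99-fold. The 4 genes of this list that fell were Ldha (23.0-fold), the Aldoa entry ENSMUSG00000114515 (9.23-fold), Hk1 (7.93-fold, or 4.51-fold without control replicate 3) and Tpi1 (3.27-fold). Counts cover whole genes, so these falls cannot be assigned to a general or a germ cell form of their transcripts. In neither list, Slc2a3, the glucose transporter GLUT3, fell 47.9-fold from 2611 ± 316 to 54.5 ± 4.59 CPM. Hk1, Tpi1, Pkm and Gapdhs share exonic sequence with other genes. Olfr1 on chromosome 11 (73393010 to 73399614) had 0 counts in control and 91 in dsfb, at least 36.7-fold higher, and its neighbour Olfr379-ps1 (73433291 to 73434224) 0 and 42, at least 16.9-fold higher.

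Of the tests below, the thinning was chosen after the other results were seen, with its bound set before its own count was known, the splits were planned, and all others, that of the depth of control replicate 3 included, were chosen after the results were seen. For the falls in general, lower depth in dsfb is not a likely account. After all libraries were thinned to the same total 6784 genes were lower, 6719 of them also lower with all reads. Members of the late spermatocyte and spermatid lists were not counted on their own in that test, so it does not decide for their low-count genes. For the fall of late spermatocyte and spermatid genes, control replicate 3 alone is not a likely account. All 20 pachytene markers were called lower without it, as were 20 of the 21 spermatid genes then tested, whose median was -4.43 in place of -6.74. A slower first wave could not be told from a loss of late cells. Leptotene and zygotene markers lay -0.5 log2 units from the autosomal Sertoli markers (95% bootstrap interval over 11 markers -1.7 to -0.06), which met the criterion set against a slower wave. That interval resamples marker genes as if independent and leaves out the spread between animals. These markers also moved both ways (6 rose and 3 fell, or 6 and 5 without control replicate 3, or 3 and 3 without dsfb replicate 1). Testes of a single age cannot separate a slower wave from a loss of late cells.

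For the higher X-linked genes, the median lay 0.03 log2 units from that of the autosomal Sertoli markers. A relative gain of the remaining cells as large as that of Sertoli cells may thus account for it. The other lists of spermatogonia, early meiotic and somatic cells had lower medians, from 0.37 (endothelial cells) to 0.86 (peritubular myoid cells). These medians by themselves do not settle whether a gain of the remaining cells accounts for the X-linked median. Above those markers 77 of 766 X-linked (10.1%) and 176 of 18987 autosomal genes (0.93%) were called, an odds ratio of 11.9 (8.92 to 15.9), but the higher X-linked median by itself raises this ratio, so it decides nothing for or against such a gain. A larger gain of a cell type outside the lists stays open. As a hypothesis, incomplete silencing of X-linked genes might add to the shift in cell makeup, which counts from whole testis cannot settle. It could be tested by counting X-linked transcripts in single spermatocytes matched for stage.

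Control replicate 3 stood apart from the other controls, with 1650 genes more than 2-fold above and 484 more than 2-fold below their mean, against 582 genes that differed 2-fold between controls 1 and 2. Its spermatid median was 3.29 log2 units higher, as a testis further along the first wave could show. Its depth of 25.7 M reads lay between those of the other controls, so depth is not a likely account.

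In the splits of the 6 libraries into 3 and 3, the real split alone (1 of 10 in each direction, for genes higher and for genes lower) reached the count of edgeR calls, with 6080 and 7176 genes, and the highest other split had 0. At unadjusted p under 0.05 edgeR called 13921 genes in the real split and 123 in the highest other. Each other split mixes libraries of both groups, which widens the spread within its groups and lowers its calls. A share of 1 in 10 is the smallest that these splits allow and lies above the preset share of 0.05. The splits therefore cannot decide whether the calls follow from the grouping.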
